A study of Mus musculus with 6 samples.

How the data were processed

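Total RNA of RAW 264.7 cells, a mouse macrophage cell line, was compared on 2-colour microarrays after 2 h with lipopolysaccharide (LPS, 100 ng/ml) and LPS-binding protein (LBP, 100 pM) or without treatment, per the labels. The series title and part of the sample descriptions write RAW 264.4, and the sample titles write RAW 264.7, the name used here. Each of 6 arrays carried 1 treated and 1 untreated RNA. On 3 arrays the untreated RNA was labelled with Cy3 and the treated RNA with Cy5. On the other 3 the dyes were swapped. The labels number the arrays of each orientation as sets 1 to 3. They do not say that the sets were separate cultures. Each p-value of a gene therefore rests only on these sets or their arrays, whose spread could be technical. The main p-values of gene lists come from the same arrays but compare the genes of a list with all other genes. They do not measure the spread between sets. The p-values of permutations and of Fisher's exact test compare genes or probes. No LPS-alone or LBP-alone sample was analysed here, so the parts of the joint treatment are not separated.

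The deposited values are log2 ratios of the channels of an array, 1 per probe and array, in a table of 16281 probes. The log base was taken from the values: between 87.3% and 92.8% of the non-zero values of each array, divided by log2 of 10, ended within 7 decimals, to 0.001 of the last one. At most 0.284% did so for the other bases tried. That is the form of a log10 ratio turned into log2. The dye normalization, the background correction and the scanner software are not given in the sources used here. Array medians lay between 0.00 and 0.02, so the ratios were close to centred as deposited. The direction was taken as Cy5 over Cy3, the likely one from the channel names in the labels, although no source states it. It was checked on 10 genes that LPS is known to induce, fixed beforehand: all 7 that were measured on every array were positive on all arrays with the treated RNA in Cy5 and negative on all swapped arrays. Spot intensities were not used here, so signal over background is unknown, and the number of arrays limits the precision.

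Exact zeros filled 10.8% of the table, between 9.12% and 12.4% of each array, far more than measured ratios with that many decimals would give. They were treated as no measurement. Zeros stood on all arrays for 998 probes and on some arrays for 2059, which left 13224 probes measured on all 6. Probes were named through the platform annotation: 13738 probes had 1 gene symbol, 52 had several and 2491 had none. Of the named probes, 13694 matched a RefSeq gene of the GRCm38.p6 annotation by gene ID, and 0 symbols needed an update. Coordinates are not printed, since no build is named for the array. Complete probes of a gene were averaged, which gave 11231 features, of which 9472 were named genes and 1759 were probes without a single symbol. Of the genes, 1808 had several complete probes, with a median range between their probes of 0.08 on the log2 scale.

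Ratios of the arrays with the treated RNA in Cy3 were multiplied by -1, so that positive values mean more transcript after LPS and LBP. The arrays with the same set number were then averaged, which cancels a dye effect and gives n = 3 sets. The mean of the sets was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, prior degrees of freedom 4.16), and p-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. "Higher", "lower", "rose" and "fell" refer to genes past it. The pairing by set number rests on the labels and on the ratios: before the signs were turned, the deviations of same-numbered arrays from the mean of their orientation correlated across features with r of 0.40, 0.43 and 0.14. The consensus correlation of the arrays of a set over all features (duplicateCorrelation) was 0.0552. Features are not independent replicates, so these correlations have no p-value. As the dyes are swapped within a set, a positive correlation of deviations marks one that follows the channels and not the treatment. On simulated data with the spread of these sets, 200 of 11231 features were changed. The test recovered 39.9% of changes of 0.3, 99.7% of changes of 1 and 100% of changes of 2 on the log2 scale. False calls were 5.42% of all calls over 20 simulations. The simulated features were independent, and fewer of them were changed than passed the threshold in the real data. The shares recovered and falsely called may therefore differ there.

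A total of 19 gene lists were fixed from textbook knowledge before the data were examined. They cover responses of macrophages to LPS, and ribosomal proteins, heat shock genes and markers of lymphocytes, fibroblasts, endothelium and epithelium as controls. Each was tested against all other features with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Fry, which asks whether the genes of a list move one way on balance, was an alternative. The genes named in the text are, by a rule fixed beforehand, the 12 named genes with the largest rise and the 12 with the largest fall that were past the threshold with the same sign on all 6 arrays. To these come up to 3 members of each list with the largest change past the threshold, and Tnf, Il1b, Il6, Il10, Nfkbia, Tnfaip3, Ptgs2, Nos2, Cxcl2, Ccl4, Tlr4, Cd14, Lbp, Actb and Gapdh whatever their result. All other genes in the text were named after their values were seen.

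Alternatives were other treatments of the sets (no block, a random block, a fixed block), centring, scaling and quantile normalization of the arrays, each probe on its own, features with missing values (at least 1 value in each orientation and values in at least 2 sets), a filter on features of little change and spread, robust moderation, a test against a 1.5-fold change, a threshold of 0.01, each dye orientation alone, and leaving out each set and each array. Zeros kept as values were added after seeing the data. Each dye effect was the intercept of a fit to the 6 unturned arrays with the treatment sign as a covariate. The gene table also gave the genomic span of 99.8% of the named genes, for comparisons of gene length.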

Results

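The data are log2 ratios of transcript level between RAW 264.7 macrophages given LPS, the endotoxin of Gram-negative bacteria, together with LBP, the serum protein that passes it to its receptor, and untreated cells. Both were cultured for 2 h. There were 6 arrays, as 3 dye-swap pairs called sets here. The comparison asks which transcripts differ after 2 h with LPS and LBP. Values are the mean log2 ratio of treated over untreated ± SD of the 3 sets, and folds are derived from that mean.

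The largest changes after 2 h with LPS and LBP were rises, several of them of cytokine and chemokine genes. The largest falls were smaller. The ranking here is among named genes measured on all arrays, past the threshold and with the same sign on every array. The largest rise was that of Acod1, which encodes the enzyme that makes itaconate, at 5.09 ± 0.19 (34.0-fold, n = 3 sets). Next among these came Il1b (3.98 ± 0.12, 15.8-fold), the surface protein gene Cd83 (3.79 ± 0.07, 13.8-fold), the chemokine gene Cxcl10 (3.70 ± 0.26, 13.0-fold) and the interferon beta gene Ifnb1 (3.58 ± 0.70, 11.9-fold). The largest falls among these were those of St8sia4, which encodes a polysialic acid synthase, by 4.38-fold (-2.13 ± 0.77), and of the transcriptional inhibitor gene Id2, by 3.42-fold (-1.77 ± 0.13). The first rank of St8sia4 rests on set 3, without which it stood at -1.69 and Id2 at -1.85. All of these had the same sign on 6 of 6 arrays, which was a condition of this ranking. Their adjusted p ran from 1.35e-06 for Acod1, Il1b and Cd83 to 0.00323 for St8sia4.

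Of 11231 features, 1663 (14.8%) passed the threshold, 826 higher and 837 lower, and 3150 had an unadjusted p under 0.05. Named genes made up 718 of the higher and 713 of the lower features. Large changes were mostly rises: 123 features rose and 10 fell by over 2-fold, and 36 rose and 1, St8sia4, fell by over 4-fold. The median fold was 1.30 among higher and 1.23 among lower features. Of the 1663 features, 1361 (81.8%) had the same sign on all 6 arrays, the arrays by whose mean they were selected. The count fell to 1056 without set 1, to 563 (352 higher, 211 lower) without set 3 and to 1104 without the array of set 3 with the treated RNA in Cy3. A test against a 1.5-fold change passed 141 features, 124 higher and 17 lower.

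**Figure D1:**
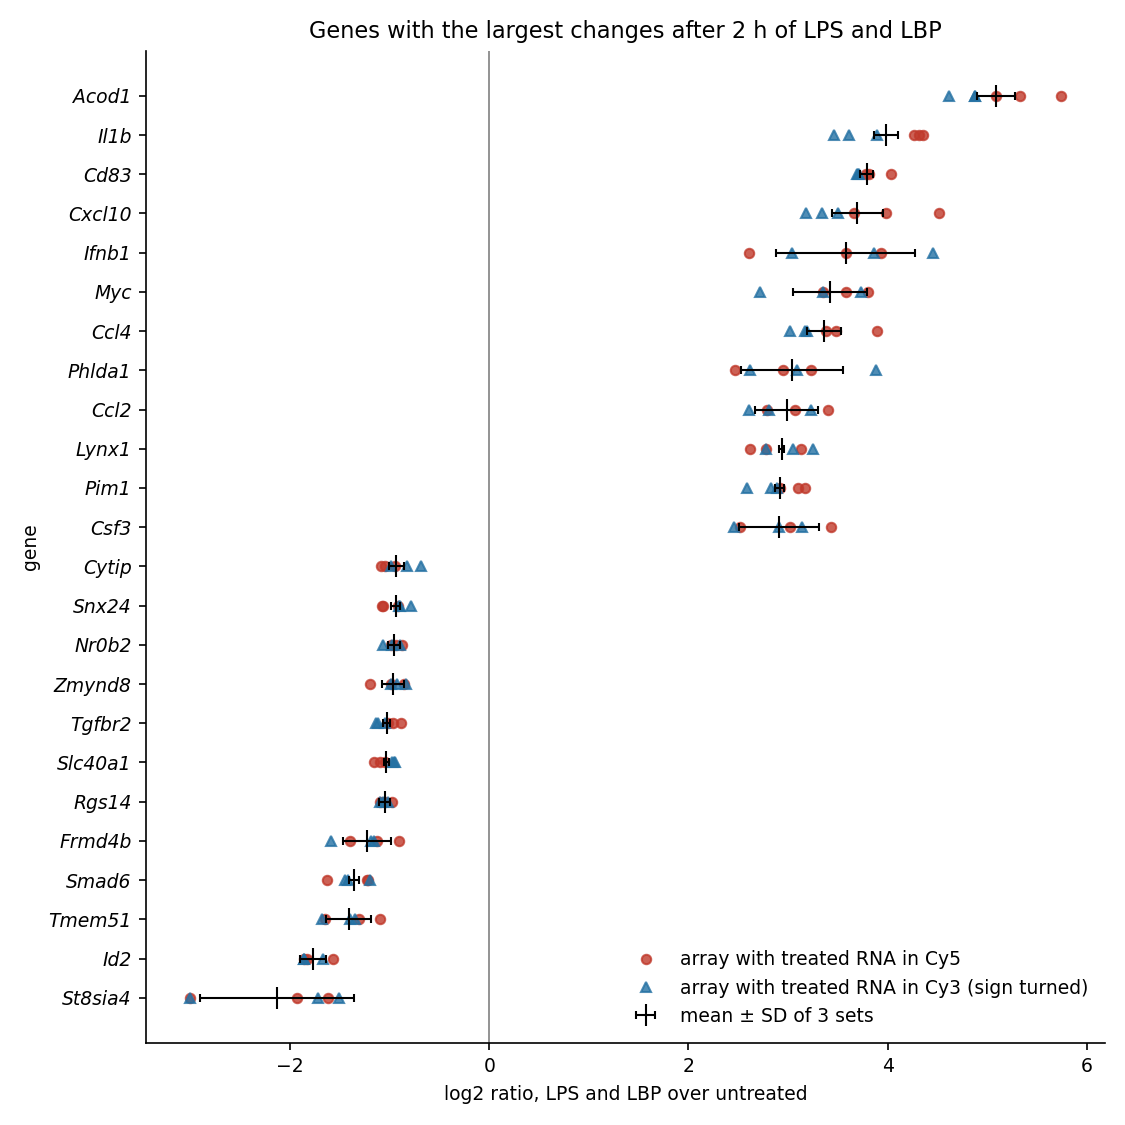
Log2 ratio of treated over untreated cells per array, with the mean ± SD of 3 sets in black. Genes are the 12 named ones with the largest rise and the 12 with the largest fall. They were chosen among those measured on all arrays, past the threshold and with the same sign on every array. Circles are arrays with the treated RNA in Cy5 and triangles are swapped arrays with the sign turned. Means run from 5.09 for Acod1 to -2.13 for St8sia4. The arrays of a gene lie on the same side of 0, as the choice requires.

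Other strongly raised genes were the transcription factor gene Myc (3.42 ± 0.37, 10.7-fold), the chemokine genes Ccl4 (3.36 ± 0.17, 10.2-fold) and Ccl2 (2.99 ± 0.31, 7.92-fold), Phlda1 (3.04 ± 0.51, 8.22-fold), the serine/threonine kinase gene Pim1 (2.91 ± 0.05, 7.54-fold) and Csf3, which encodes the growth factor of granulocytes (2.91 ± 0.40, 7.52-fold). Adjusted p was at most 0.000164 for each, and all were higher on 6 of 6 arrays. Lynx1, a gene of the Ly6 family, stood at 2.93 ± 0.02 on the only probe measured on all arrays. A second Lynx1 probe, measured on 5 arrays, had a mean of -0.13. A second Csf3 probe, measured on 4 arrays, lay between -3.36 and 2.84, with a mean of -0.75. Before the signs were turned, this Csf3 probe leaned to Cy3 and the second Lynx1 probe to Cy5 on every array with a value. That is the mark of a dye effect, so these means say little about the treatment.

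Inflammatory cytokines rose as a group, with 14 of 20 tested members higher, 0 lower and 6 not past the threshold by limma (14 higher adjusted over the list alone, and 0 lower at an unadjusted p under 0.05). The median of the list was 0.93, and camera gave adjusted p = 2.49e-14, against adjusted p = 0.115 with an estimated correlation. Besides Il1b, Ifnb1 and Csf3, Tnf rose 4.44-fold (2.15 ± 0.18, adjusted p = 2.23e-05), and Il10, which encodes an anti-inflammatory cytokine, rose 4.18-fold (2.06 ± 0.17, adjusted p = 2.25e-05), each on 6 of 6 arrays. Il6 rose 2.21-fold (1.14 ± 0.42, adjusted p = 0.00399, 6 of 6 arrays), but its adjusted p was 0.0538 without set 3 and 0.0557 with only the arrays with the treated RNA in Cy3. Among members that did not pass, Il12b, a subunit of interleukin 12, stood at -0.00 ± 0.11 (adjusted p = 0.974).

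Chemokines showed 9 of 15 tested members higher and 0 lower by limma (9 higher adjusted over the list alone, 0 lower at an unadjusted p under 0.05), with a median of 0.63. The list stood above other genes with camera adjusted p = 2.64e-08, and adjusted p = 0.239 with an estimated correlation. Cxcl10, Ccl4 and Ccl2 led the list, followed by Cxcl11, Cxcl16, Ccl5, Ccl20, Ccl22 and Ccl9. Cxcl2, which encodes a neutrophil attractant, had no probe measured on all arrays. With missing values allowed, its 2 probes together gave 3.91 (15.0-fold, adjusted p = 0.0159), higher on 6 of 6 arrays. The better measured probe lay between 4.04 and 6.09 on 5 arrays, with a mean of 4.95, and a second probe, measured on 2 arrays, gave -2.94 and 2.76. Both values of the second probe leaned to Cy3 before the signs were turned, whichever dye held the treated RNA. This probe alone gave the value of the swapped array of set 1. The 15.0-fold and the 6 of 6 arrays therefore depend on it. Ccl3 was measured on 1 array, at 2.76.

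Genes of the NF-κB family and its feedback regulators formed the list with the highest median, 1.52, and 13 of 14 tested members were higher and 0 lower by limma (13 higher adjusted over the list alone, 0 lower at an unadjusted p under 0.05). Camera gave adjusted p = 2.95e-19, and adjusted p = 0.115 with an estimated correlation. Nfkbiz, which encodes an atypical IκB protein, rose 6.09-fold (2.61 ± 0.32), the adaptor gene Traf1 6.02-fold (2.59 ± 0.23) and Tnfaip2 4.45-fold (2.15 ± 0.08), with adjusted p of at most 5.54e-05. Tnfaip3, which encodes the ubiquitin-editing inhibitor A20, rose 2.79-fold (1.48 ± 0.03, adjusted p = 1.62e-05). All 4 were higher on 6 of 6 arrays. The Nfkbiz value is the mean of probes at 1.60 and 3.61, and that of Tnfaip3 the mean of probes at 0.96 and 2.01. The subunit genes Relb, Nfkb2, Rel and Rela also rose, Relb by 3.46-fold and Rela by 1.31-fold. Nfkbia, the gene of the main IκB protein, had a value on 1 array, 1.96.

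Immediate early transcription factors included 17 higher and 3 lower genes among 22 tested (17 and 4 adjusted over the list alone), with a median of 0.68. By camera the list had adjusted p = 1.63e-10, and adjusted p = 0.115 with an estimated correlation. After Myc, the largest rises were those of Cebpd (1.74 ± 0.08, 3.33-fold, adjusted p = 1.62e-05) and Ier3 (1.68 ± 0.15, 3.21-fold, adjusted p = 3.24e-05), both on 6 of 6 arrays. The lower genes were the Krüppel-like factors Klf2 (-0.64 ± 0.10) and Klf4 (-0.47 ± 0.19) and the AP-1 subunit gene Jun (-0.35 ± 0.19), with adjusted p of at most 0.0302.

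Feedback regulators of kinases, cytokine signalling and mRNA decay had 12 higher and 2 lower members among 18 tested (12 and 2 adjusted over the list alone), and a median of 0.76. By camera the adjusted p was 1.67e-09, and adjusted p = 0.115 with an estimated correlation. Pim1 led, followed by the stress genes Gadd45b (2.38 ± 0.11, 5.20-fold, adjusted p = 9.16e-06) and Gadd45a (2.01 ± 0.21, 4.03-fold, adjusted p = 3.71e-05), higher on 6 of 6 arrays. Gadd45g, of the same family, was lower by 1.13-fold (-0.18 ± 0.00, adjusted p = 0.0450, 5 of 6 arrays), as was Zfp36l2 by 1.25-fold (-0.33 ± 0.08). The dual-specificity phosphatase genes Dusp2, Dusp16, Dusp1 and Dusp8 and the mRNA-decay gene Zfp36 were among the higher members. The cytokine signalling inhibitor gene Socs3 stood at 0.09 ± 0.06 (adjusted p = 0.281).

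**Figure D2:**
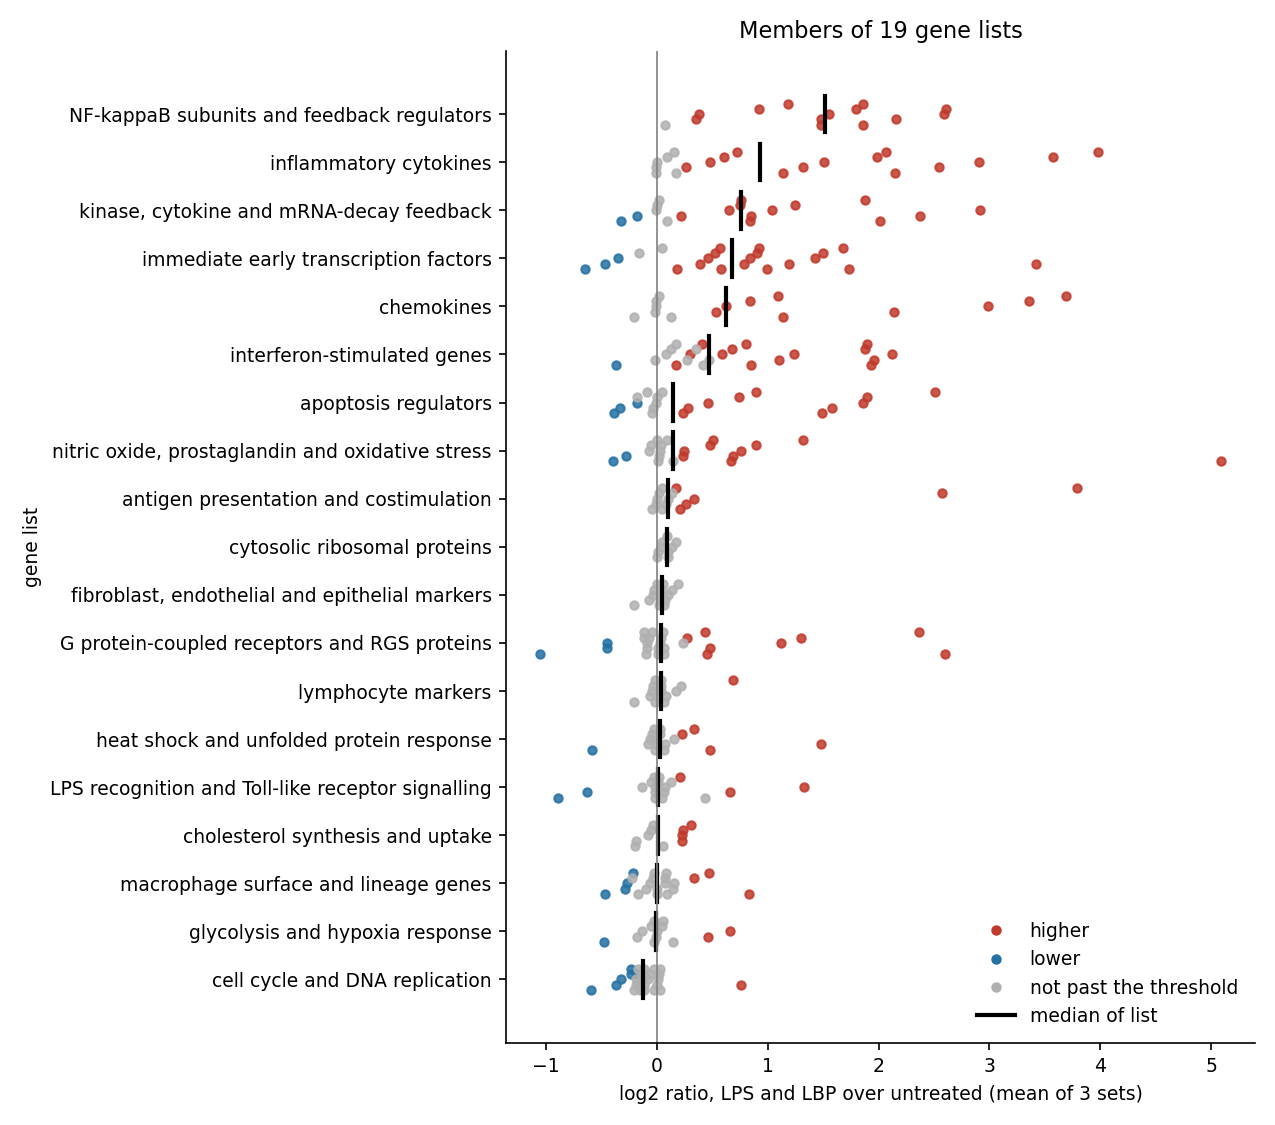
Mean log2 ratio of treated over untreated cells for each tested member of 19 gene lists. Points are genes, red for higher, blue for lower and grey for not past the threshold, and black bars are list medians. The medians run from 1.52 for the NF-κB list to -0.13 for the cell cycle list.

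Interferon-stimulated genes had 14 higher and 1 lower member among 23 tested (16 and 1 adjusted over the list alone), with a median of 0.48. Camera gave adjusted p = 1.9e-09, and adjusted p = 0.424 with an estimated correlation, which was 0.82 for this list. Fry gave adjusted p = 0.0735. Mx2, which encodes an antiviral GTPase, rose 4.35-fold (2.12 ± 0.28, adjusted p = 7.71e-05), the ubiquitin-like modifier gene Isg15 3.89-fold (1.96 ± 0.64, adjusted p = 0.00227) and Ifit3 3.81-fold (1.93 ± 0.27, adjusted p = 0.000105), each on 6 of 6 arrays. The lower member was the GTPase gene Ifi47 (-0.37 ± 0.04, adjusted p = 0.0035). The sets differed: the list's median was 1.05 in set 1, 0.35 in set 2 and 0.29 in set 3, and Isg15 stood at 2.64, 1.88 and 1.36. Without set 1, 11 members were higher and 1 lower, the median was 0.28 and camera gave adjusted p = 1.27e-08. The NF-κB list had medians of 1.63, 1.51 and 1.54 in the 3 sets.

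**Figure D3:**
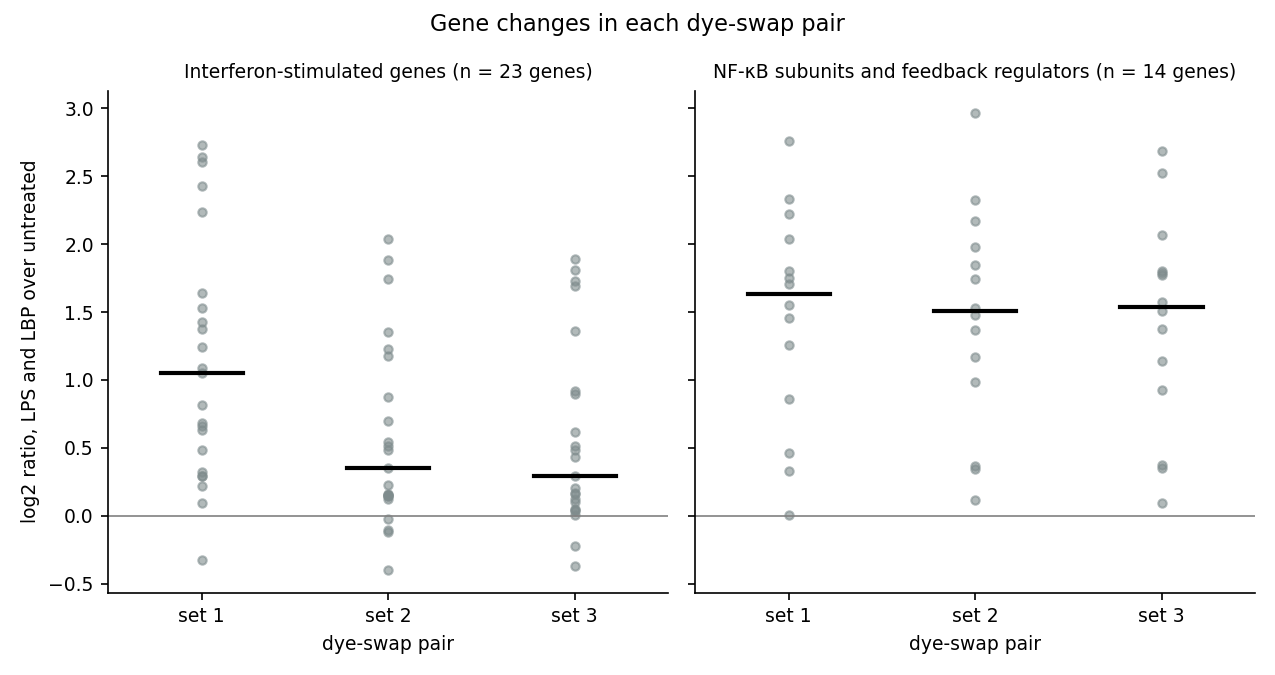
Log2 ratio of treated over untreated cells in each dye-swap pair for 23 interferon-stimulated genes, left, and 14 genes of the NF-κB list, right. Points are genes and black bars are medians, which are 1.05, 0.35 and 0.29 on the left and 1.63, 1.51 and 1.54 on the right.

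Among 5 Toll-like receptor genes tested, 2 rose, 1 fell and 2 did not pass. Tlr2, the receptor of bacterial lipoproteins, rose 2.51-fold (1.33 ± 0.03, adjusted p = 2.23e-05, 6 of 6 arrays), and Tlr1 rose 1.58-fold (0.66 ± 0.16, adjusted p = 0.00172, 6 of 6 arrays), with adjusted p = 0.0814 on the arrays with the treated RNA in Cy5 alone. Tlr4, the signalling receptor of LPS, fell by 0.89 ± 0.02 on the log2 scale, or 1.85-fold (adjusted p = 8.96e-05, 6 of 6 arrays). Its 3 probes had means of -1.35, -1.12 and -0.20. Tlr9 (0.44 ± 0.32, adjusted p = 0.0523) and Tlr3 (-0.02 ± 0.13, adjusted p = 0.895) did not pass. The co-receptor gene Cd14 (-0.02 ± 0.07, adjusted p = 0.837) and Lbp itself (-0.02 ± 0.16, adjusted p = 0.891) did not pass. The list of LPS recognition and signalling genes had 3 higher, 2 lower and 13 genes not past the threshold, Myd88 being the other higher and Tab1 the other lower one (4 and 2 adjusted over the list alone). It did not stand apart from other genes (median 0.01, camera adjusted p = 0.346).

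Macrophage surface and lineage genes were mixed, with 3 higher, 4 lower and 14 not past the threshold (4 and 6 adjusted over the list alone), a median of 0.00 and camera adjusted p = 0.896. Adgre1, which encodes a surface marker of macrophages, rose 1.78-fold (0.83 ± 0.07, adjusted p = 0.000195) and Spi1, the gene of the lineage factor PU.1, 1.38-fold (0.47 ± 0.12, adjusted p = 0.00349), each on 6 of 6 arrays. With only the arrays with the treated RNA in Cy3, Spi1 had adjusted p = 0.0597. Fcgr1, a high-affinity antibody receptor gene, fell 1.38-fold (-0.47 ± 0.09, adjusted p = 0.00231, 6 of 6 arrays). Csf1r, Trem2 and Fcgr3 were also lower, and Fcgr2b was higher.

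Genes of nitric oxide, prostaglandin and oxidative stress responses had 10 higher and 2 lower members among 21 tested (10 and 2 adjusted over the list alone), with a median of 0.14. Camera gave adjusted p = 9.92e-05, and adjusted p = 0.295 with an estimated correlation. After Acod1, the prostaglandin synthase gene Ptgs2 rose 2.49-fold (1.32 ± 0.44, adjusted p = 0.00273) and the metallothionein gene Mt2 1.86-fold (0.89 ± 0.19, adjusted p = 0.000851), each on 6 of 6 arrays. Ptgs2 ranged from 0.05 to 2.01 between arrays, and its adjusted p was 0.21 with only the arrays with the treated RNA in Cy5. Nos2, the inducible nitric oxide synthase gene, did not pass at 2 h (0.09 ± 0.03, adjusted p = 0.256). The lower genes were Pla2g4a and Gclc, which encode a phospholipase and an enzyme of glutathione synthesis.

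Apoptosis regulators had 10 higher and 3 lower members among 20 tested (10 and 4 adjusted over the list alone), a median of 0.14 and camera adjusted p = 0.00127, with adjusted p = 0.249 with an estimated correlation. The death receptor gene Fas rose 5.69-fold (2.51 ± 0.23, adjusted p = 2.33e-05). The survival genes Bcl2a1d and Bcl2a1a rose 3.73-fold (1.90 ± 0.14, adjusted p = 2.23e-05) and 3.62-fold (1.86 ± 0.17, adjusted p = 3.14e-05). All 3 were higher on 6 of 6 arrays. The Bcl2a1 genes are near-identical copies, and whether their probes tell them apart was not tested here. Lower members were Bcl2 (-0.38 ± 0.03), Apaf1 (-0.34 ± 0.06) and Bbc3 (-0.18 ± 0.03), with adjusted p of at most 0.0478. The list's camera adjusted p was 0.0556 with only the arrays with the treated RNA in Cy5.

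Antigen presentation and costimulation genes had 6 higher and 0 lower members among 15 tested by limma (6 higher adjusted over the list alone, 0 lower at an unadjusted p under 0.05), with a median of 0.10. This list had camera adjusted p = 0.000396, and adjusted p = 0.203 with an estimated correlation. After Cd83 came the costimulatory receptor gene Cd40 (2.57 ± 0.51, 5.93-fold, adjusted p = 0.000332) and, far smaller, the peptide loading gene Tapbp (0.34 ± 0.11, 1.26-fold, adjusted p = 0.0112), both on 6 of 6 arrays. Tapbp had an adjusted p of 0.058 without set 1 and 0.126 without set 3, and stood at 0.16 (adjusted p = 0.238) with only the arrays with the treated RNA in Cy3. H2-K1, H2-D1 and Cd74 made up the rest.

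Cell cycle and DNA replication genes were the list that fell, with 1 higher and 6 lower members among 27 tested (1 and 13 adjusted over the list alone) and a median of -0.13. Camera gave adjusted p = 0.000284, and adjusted p = 0.203 with an estimated correlation. The replication licensing gene Cdc6 fell 1.51-fold (-0.60 ± 0.11, adjusted p = 0.00118, 6 of 6 arrays), and Cdkn1b, Ccna2, Ccne1 and Mcm4 were also lower. Ccne2, which encodes cyclin E2, was lower at -0.37 ± 0.13 (adjusted p = 0.0107, 5 of 6 arrays). That value came from the arrays with the treated RNA in Cy5 (-0.73) and not from the swapped ones (-0.02), and its adjusted p was 0.124 without set 3 and 0.0804 to 0.267 without any single array but that of set 1 with the treated RNA in Cy5. In limma fits to the 6 single arrays, Ccne2 had adjusted p = 0.0776 with the set as a random block and 0.0927 with no block. The higher member was Cdkn1a, the gene of the cell cycle inhibitor p21, at 1.70-fold (0.76 ± 0.10, adjusted p = 0.000394, 6 of 6 arrays).

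Cholesterol synthesis and uptake genes had 4 higher and 0 lower members among 10 tested by limma (4 and 2 adjusted over the list alone, and the same at an unadjusted p under 0.05), a median of 0.01 and camera adjusted p = 0.367. Sc5d (0.31 ± 0.09), Idi1 (0.23 ± 0.07) and Cyp51 (0.23 ± 0.06) of the synthesis pathway rose by 1.24-fold or less, with adjusted p of at most 0.0269, on 6 of 6 arrays, and Msmo1 was the other higher one. Without set 3 the adjusted p of Sc5d, Idi1 and Cyp51 was 0.135, 0.144 and 0.225, and without set 1 that of Idi1 and Cyp51 was 0.0929 and 0.0721. None of these 3 passed in either dye orientation alone (adjusted p from 0.0624 to 0.128). Glycolysis and hypoxia genes had 2 higher and 1 lower member among 13 tested (2 and 1 adjusted over the list alone), a median of -0.01 and camera adjusted p = 0.75. The glucose transporter gene Slc2a1 rose 1.58-fold (0.66 ± 0.06, adjusted p = 0.000435) and Vegfa 1.38-fold (0.46 ± 0.09, adjusted p = 0.00263), each on 6 of 6 arrays. Pfkfb3, which encodes a regulator of glycolysis, fell 1.39-fold (-0.48 ± 0.13, adjusted p = 0.00422, 6 of 6 arrays), with adjusted p = 0.0595 without set 3 and 0.061 with only the arrays with the treated RNA in Cy5. Vegfa had adjusted p = 0.0525 with only the swapped arrays.

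G protein-coupled receptors and RGS proteins, which end G protein signals, had 8 higher and 3 lower members among 26 tested (9 and 3 adjusted over the list alone), a median of 0.04 and camera adjusted p = 0.0865. The fatty acid receptor gene Gpr84 rose 6.06-fold (2.60 ± 0.15, adjusted p = 1.07e-05), Rgs16 5.16-fold (2.37 ± 0.16, adjusted p = 1.62e-05) and Rgs1 2.46-fold (1.30 ± 0.15, adjusted p = 0.000104), each on 6 of 6 arrays. Rgs14 fell 2.07-fold (-1.05 ± 0.05, adjusted p = 5.61e-05, 6 of 6 arrays), and the receptor genes P2ry12 and Ptgir were also lower. The list's camera adjusted p was 0.00396 without set 2, 0.0461 with only the arrays with the treated RNA in Cy3 and 0.0183 with each probe on its own.

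Heat shock and unfolded protein response genes had 4 higher and 1 lower member among 17 tested (5 and 1 adjusted over the list alone), a median of 0.03 and camera adjusted p = 0.127. Herpud1, a gene of protein degradation at the endoplasmic reticulum, rose 2.79-fold (1.48 ± 0.04, adjusted p = 1.63e-05) and Ddit3 1.40-fold (0.48 ± 0.09, adjusted p = 0.00216), each on 6 of 6 arrays. A second Herpud1 probe, measured on 5 arrays, lay between -0.40 and 0.69, with a mean of 0.14. Its values all leaned to Cy3 before the signs were turned, whichever dye held the treated RNA. Hspa8 and Hspa5 were the other higher members. The unfolded protein response factor gene Xbp1 fell by 0.59 on the log2 scale (SD 0.11, adjusted p = 0.00126, 6 of 6 arrays). With only the arrays with the treated RNA in Cy3, Ddit3 had adjusted p = 0.0686 and the list 0.0108, and fry gave the list 0.0284.

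No control list passed camera in the main test. The list of cytosolic ribosomal proteins does not hold all such genes, since 23 genes with the symbol root Rpl alone were measured on all arrays. Of its 31 members on the array, only 9 were measured on all arrays. Of these, 0 were higher and 0 lower by limma or adjusted over the list alone, and 2 were higher at an unadjusted p under 0.05. The list had a median of 0.09 and camera adjusted p = 0.0698. That adjusted p was 0.0257 without set 1 and 0.036 without the array of set 1 with the treated RNA in Cy3. Lymphocyte markers had 1 higher member among 15 (1 adjusted over the list alone), the inhibitory receptor gene Cd22 (0.68 ± 0.19, 1.61-fold, adjusted p = 0.00231, 6 of 6 arrays), and camera adjusted p = 0.333. A second Cd22 probe, measured on 5 arrays, lay between -0.78 and 0.49, with a mean of -0.11. Its values all leaned to Cy5 before the signs were turned, whichever dye held the treated RNA. With only the arrays with the treated RNA in Cy3, Cd22 had adjusted p = 0.0755. Markers of fibroblasts, endothelium and epithelium had 0 of 15 members past the threshold by limma, also adjusted over the list alone, and 2 higher at an unadjusted p under 0.05 (median 0.05, camera adjusted p = 0.34). Actb stood at 0.22 ± 0.26 (adjusted p = 0.211), but passed without set 1 (0.37, adjusted p = 0.0214). Gapdh, averaged over 11 probes, stood at -0.02 ± 0.00 (adjusted p = 0.81).

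Other genes among the 12 largest falls lay between 1.91-fold and 2.66-fold. The inhibitory SMAD gene Smad6 fell 2.56-fold (-1.35 ± 0.05, adjusted p = 2.23e-05) and the TGF-β receptor gene Tgfbr2 2.04-fold (-1.03 ± 0.03, adjusted p = 5.12e-05). Tmem51 fell 2.66-fold (-1.41 ± 0.23), Frmd4b 2.34-fold (-1.23 ± 0.24) and Slc40a1, which encodes the iron exporter ferroportin, 2.04-fold (-1.03 ± 0.03). The chromatin reader gene Zmynd8 (-0.96 ± 0.11), the orphan nuclear receptor gene Nr0b2 (-0.96 ± 0.06), the sorting nexin gene Snx24 (-0.94 ± 0.04) and Cytip, whose product binds cytohesins (-0.93 ± 0.07), fell by 1.91-fold to 1.95-fold. Adjusted p was at most 0.00045 for each, and all were lower on 6 of 6 arrays.

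The arrays were compared across features. Arrays of the same dye orientation correlated with r between 0.50 and 0.73, and arrays of opposite orientation with r between -0.65 and -0.12 before the signs were turned. The means of the 3 sets correlated with r between 0.77 and 0.85. A dye effect passed the threshold for 56 features, 32 toward Cy5 and 24 toward Cy3, and 2832 had an unadjusted p under 0.05. Of these 56, 6 were also among the 1663 features changed by the treatment. With the set as a random block 34 features had a dye effect. Of the 1808 genes with several probes, 445 had any probe past the threshold and 193 had all of them past it. Probes past it in opposite directions were found for 4, Brca2, Clec5a, Fabp5 and Inpp5e. Among the named genes not yet mentioned for this, probe means differed by over 1.5-fold for Cdkn1a (0.28, 0.94 and 1.07), Ifit3 (1.37 and 2.49), Fas (2.20 and 2.82), Gadd45a (1.68 and 2.34) and Il1b (3.64, 3.94 and 4.36), each on probes measured on all arrays.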

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

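Of 91 named genes and list medians, 4 had 1 of the 6 arrays far from the other 5, a number near the 1 in 20 that chance gives. Cd83 stood at 4.04 on the array of set 2 with the treated RNA in Cy5, against 3.70 to 3.81 on the others. Tnf stood at 2.57 on the same array, against 1.96 to 2.18. The median of the lymphocyte markers was 0.36 on the array of set 1 with the treated RNA in Cy5, against -0.10 to 0.06. The median of the G protein-coupled receptors and RGS proteins was 0.22 on the array of set 3 with the treated RNA in Cy3, against 0.02 to 0.04. These values were not weighed further.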

How the results depend on the processing

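Over 24 other settings for genes and 25 for lists, no named gene or list past the threshold changed sign. None that was not past it passed with the other sign. Without passing, signs could change, as that of Lbp did without set 3 (0.07). Of the named gene values 1668 kept their side of the threshold, 59 lost it and 1 gained it. With each probe on its own, only the first complete probe of a gene was counted, so its other probes do not enter. Of the 1663 changed features (826 higher, 837 lower), a test against 1.5-fold kept 141 (124 higher, 17 lower) and a threshold of 0.01 kept 835 (475, 360). Only the arrays with the treated RNA in Cy5 passed 639 (347, 292) and only the others 655 (408, 247), with fewer arrays by construction. Leaving out a set or an array gave 563 to 1685 features, 352 to 854 higher and 211 to 831 lower. With the pairing set aside, the 6 arrays with no replicate block passed 1865. With the set as a random block they passed 1933. As a fixed block they passed 1663, which is the main test in another form and so no separate check. Of the named genes, 20 lost their call against 1.5-fold, 7 with only the Cy5 arrays, 10 with only the Cy3 arrays, 7 without set 3 and 3 without set 1. In these fits 1 named gene, Ccne2, lost its call, both with a random block (adjusted p = 0.0776) and with no block (0.0927). The random block lowered the count of dye effects from 56, with no block, to 34. The cause was not tested.

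Every list past the threshold lost it with an estimated correlation: adjusted p was 0.115 for cytokines, NF-κB genes, immediate early factors and feedback regulators, 0.239 for chemokines, 0.424 for interferon-stimulated genes, 0.203 for cell cycle and antigen presentation genes, 0.295 for nitric oxide, prostaglandin and oxidative stress genes and 0.249 for apoptosis regulators. With an estimated correlation, camera rests on the residual degrees of freedom of only 3 sets. The loss alone therefore does not show that members of a list are correlated. The estimated correlation was -0.0444 for NF-κB genes, -0.0277 for immediate early factors and -0.0398 for feedback regulators, against 0.82 for interferon-stimulated genes. With fry, interferon-stimulated genes had 0.0735 and heat shock genes 0.0284. With only the Cy5 arrays, apoptosis regulators had 0.0556. With only the Cy3 arrays, heat shock genes had 0.0108 and G protein-coupled receptors and RGS proteins 0.0461, and 0.0183 with each probe on its own. Leaving out a set or an array gave the latter 0.00396 to 0.363 and ribosomal proteins 0.0257 to 0.402. Zeros kept as values, a setting chosen after seeing the data, gave 1439 features. Signal over background is unknown.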

Other observations

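The tests on gene lists, zeros, set numbers and the set 1 interferon response, and that on genes raised over 2-fold, were chosen after the result was seen, except that of a single deviating array. A list of DNA replication and repair genes beyond the fixed cell cycle list was drawn up after 12 of its genes, most of them lower, had been seen, and these are left out here. Of the 32 other tested members, 5 fell, Brca1 (1.34-fold, -0.42 ± 0.04), Atm, Ercc5, Chek1 and Dbf4, 1, Ercc1, rose (1.29-fold, 0.37 ± 0.09) and 26 did not pass. Their median was -0.084 and limma's camera gave adjusted p = 0.008 over 6 such tests, against an unadjusted p = 0.0752 with an estimated correlation. A small shift of the whole group is a hypothesis consistent with the first of these values.

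The falls of Smad6, Id2 and Tgfbr2 were not part of a shift of TGF-β and BMP genes that could be detected. Skil (2.13-fold, 1.09 ± 0.04) and Tgfb1 (1.40-fold, 0.48 ± 0.04), also seen before the list of these genes was drawn up, rose. Over the whole list 5 members rose and 6 fell. Of the 28 such genes not seen before the list was drawn up, 3 rose, Id1 (1.23-fold, 0.30 ± 0.03), Tgif1 and Id3, and 3 fell, Acvr1 (1.34-fold, -0.43 ± 0.08), Acvr2b and Bmpr1a. They had a median of 0.0025 (camera adjusted p = 0.824) and moved both ways. No shared shift was seen among them, though a small one is not excluded. The fall of Slc40a1 stood beside rises of the iron transporter genes Slc11a2 (1.34-fold, 0.42 ± 0.05) and Slc11a1 (1.25-fold, 0.32 ± 0.03). The 11 iron handling genes not seen before had a median of 0.0326 (camera adjusted p = 0.403), which does not show a shift of the group either way.

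Genes raised by over 2-fold were short. The 112 named ones had a median genomic span of 7.76 kb, against 18.8 kb for 8025 genes not past the threshold, a difference of -0.38 on the log10 scale (permutation p = 1e-05, the smallest that 100000 resamples can give, two-sided). Over all 718 higher genes the difference was -0.0466 (permutation p = 0.0864). The 713 lower genes were longer, at 22.9 kb, with a difference of 0.0869 (permutation p = 0.00149), against the prediction that they would be short. The permutations treat genes as independent, and near-identical copies such as the Bcl2a1 genes are not, so these p-values may be too small. A link between a short span and a large early rise may hold, as a hypothesis, and no explanation for it was tested.

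The 23 interferon-stimulated genes were all higher in set 1 than the mean of sets 2 and 3, by a median of 0.48, the largest such difference of the 19 lists, while the NF-κB list differed by 0.03 and the cytokines by 0.10. A larger scale of all ratios in set 1 is argued against: the slope of set 1 on the other sets over 1648 other changed genes was 1.06, and after dividing by it the median excess was 0.45, with quartiles of 0.24 and 0.79. A single deviating array is argued against too, since the excess was 0.61 with the treated RNA in Cy5 and 0.45 with it in Cy3. Ifnb1 was higher in set 1 (4.19) than in sets 2 (2.82) and 3 (3.72), by 0.92 over their mean, but its lead over set 3 is within the SD of the sets, 0.70, so more interferon beta in set 1 may contribute and stays open. The design gives no group that separates the sets, and no other biological explanation was tested.

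Arrays with the same set number deviated together before the signs were turned, with a lowest correlation of 0.14. That value is the pattern itself and was seen first. Because the dyes are swapped within a set, a treatment effect that differed between sets would have made these correlations negative. The values of 0.40, 0.43 and 0.14 argue against that as the main source of the shared deviation, which followed the channels. What caused it was not tested. The zeros were uneven. Of the 31 probes of the ribosomal protein list, 71.0% held at least 1 zero, against 16.4% of other named probes (odds ratio 12.4, Fisher's exact p = 2.58e-11). Spots at the upper limit of the scanner could give this. Markers of other cell types held zeros in 26% of 50 probes (odds ratio 1.78, 95% interval 0.865 to 3.43, Fisher's exact p = 0.0842). Dim spots therefore stay open as a second source.

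The split of the 6 arrays by their labels gave 1865 features in a fit with a dye term, and the highest of the other splits gave 0 by limma (3071 and at most 1090 at an unadjusted p under 0.05). Of the 10 splits, 4 part every same-numbered pair, the labelled one included, and 1 gave as many features as the labelled one, itself. With 10 splits no share can fall under 0.05. In every other split most of the treatment effect enters the residual spread, which lowers the count, so 0 is no measure of chance.

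Among features not measured on all arrays, 1100 had at least 1 value in each orientation on a probe and values in at least 2 sets, of which 23 were higher and 22 lower. Members of the fixed lists among them, all higher with adjusted p of at most 0.0159, were Cxcl2, the interferon response factor gene Irf1 at 0.99 (1.98-fold, 5 of 5 arrays), Ccl7 at 0.83 (6 of 6 arrays), Ebi3 at 0.50 (3 of 4 arrays) and Oas1a at 0.35 (4 of 4 arrays). For Ebi3 and Oas1a, sets 2 and 3 held only swapped arrays, so a dye effect does not cancel there. Ebi3 stood at -0.08 on its only array with the treated RNA in Cy5 and at 0.46 to 0.86 on the swapped arrays. Its rise cannot be told apart from a dye effect. Oas1a stood at 0.33 on its array with the treated RNA in Cy5. The 3 probes of Ccl7, each measured on 4 or 5 arrays, had means of 1.89, 0.81 and 0.21. Of 290 groups of genes that share the root of their symbol, 2 passed camera, those of Bcl (18 members, 11 higher and 1 lower, adjusted p = 1.82e-06) and Ccl (18 members, 6 higher, adjusted p = 0.0427), and both had adjusted p = 0.992 with an estimated correlation. The Bcl root joins genes of different function, such as the survival gene Bcl2l1 and the transcription factor gene Bcl6.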
